A study of Rattus norvegicus with 18 samples.

How the data were processed

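RNA from epiblast and primordial germ cells (PGC) of rats carrying the Prdm14-Venus reporter was extracted with a PicoPure kit and amplified with a SMART-Seq v4 ultra low input kit, per the labels' protocols. The data comprised 18 libraries: 6 of epiblast at E7.25 and E7.75, and 12 of PGC at E9.5, E10.5, E11.5, E12.5 and E15.5. Groups were taken from the sample titles. Sex is labelled for epiblast and for E15.5 PGC only.

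The values deposited by the authors were RPKM (read numbers scaled to gene length in kilobases and to the mapped reads of a library), in 1 table of the series with 1 column per library, per the labels. The submitters' processing notes name bcl2fastq 2.18.0.12, cutadapt 1.14, TopHat2 2.1.0, Cufflinks 2.2.1 and the build rn6, without role or order. The annotation release, the treatment of multi-mapping reads and the use of strand are not given in the sources used here. Genes with near-identical copies or several lines per symbol (Lefty2, Ddx3y, Mt1, Mt1m, Mt2A, Ifitm1, the globins, Dppa3, Rpl39l and Rpl30) are therefore uncertain. RPKM divides by the mapped total of each library, so a change in a few abundant genes shifts the rest, and short genes and small RNA genes are sensitive to the length used. The table had 32545 lines, each with an identifier and a symbol. The symbols of the file were used as given, since 0 identifiers matched the reference table. No rn6 annotation was used here, so positions in the genome are not analysed here and the planned list of X-linked genes from chromosome annotation was not run.

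The table holds no read counts. For each library, values under 50 RPKM were divided by those of the same genes in the E7.75 female library. The inverse of the most common ratio was taken as relative depth, which assumes that genes with the same few reads give this ratio. It rested on 43 to 81 genes per library at E10.5 and E11.5 and on 79 to 160 in the others, of 8297 to 10805 compared. Relative to the E7.75 female library, depth was 82.6% to 120.9% in 14 libraries and 20.7% to 23.0% in the 4 libraries of E10.5 and E11.5. Among tested genes 21.35% and 21.61% were listed at 0 in the E10.5 libraries, 14.36% and 14.96% in those of E11.5, and 8.30% to 15.4% in the others. The column sums lay between 587609 and 849182 RPKM. Columns with values of samples outside the series numbered 0. No pair of replicates shared more than 0.00673% identical values, so none was treated as a library deposited more than once.

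Values were transformed to log2(RPKM + 1), with a pseudocount of 1. Genes with an RPKM of at least 1 in at least 2 libraries were tested, which left 14865. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a moderated variance that follows the mean level. For 7 comparisons the model had 8 groups (10 residual degrees of freedom), with the sexes of epiblast together and those of E15.5 PGC as separate groups. For the 3 comparisons of sex it had 10 groups (8 residual degrees of freedom). All libraries shared 1 estimate of the spread, because most groups have 2 libraries. Replicates were not equally close. Their median absolute log2 difference was 0.404 at E9.5, 0.335 at E10.5 and 0.332 in female E15.5 PGC, against 0.221 to 0.273 in the other groups. The shared spread can thus be too small for comparisons with E9.5, E10.5 or female E15.5 PGC, and their p-values too low. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera in limma, with the correlation between genes estimated for each list and with adjustment over all lists within a comparison. The lists numbered 29, with 1 list of X-linked genes added from general knowledge. Beside the main test, camera with a preset correlation of 0.01 and fry were run. A list that passed with the preset correlation but not with the estimated one is given with the second adjusted p. Of 293 list tests 50 passed with the estimated correlation, 94 with the preset one and 128 with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

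The groups, the comparisons, the tests, the 29 lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. By the rule, each comparison names the 5 genes that passed with the largest rise and the 5 with the largest fall, among genes with a mean of at least 5 RPKM in the higher group and no overlap between the libraries compared. Per list, it adds the 2 largest rises, the 2 largest falls and the highest member that did not pass. The 10 germ line genes are followed in every comparison, and Stra8, Nanos2, Dnmt3l and Y-linked genes in the comparisons of sex. For the difference of the sex differences, which involves 4 sets of libraries, the condition of no overlap was not applied. The text names 5 to 48 genes per comparison, where about 20 to 30 per main comparison had been planned. Small RNA genes held 1 to 9 of the top 10 places in most comparisons, and were counted but not named; the genes named in their place were chosen after the values were seen. Xist was not among the tested genes. For 1 gene that the rule selects, the result is not reported here.

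The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 RPKM, rescaling to TPM, scaling by the median of ratios, quantile normalization, variances without a trend or with robust estimation, fits on the compared libraries only, the replicate number as a block, the 10-group model throughout, a minimum log2 fold change of 1, adjustment over all comparisons together, PGC of E9.5 to E12.5 only, and each library left out in turn. Fits without the E10.5 and E11.5 libraries, counts without small RNA genes, and a comparison of E12.5 with E9.5 were added after the data had been seen. A fit that left a group with 1 library assumes that this library varies like the other groups.

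The model was tested on simulated data with 200 changed genes among 14865. Of genes changed by a log2 difference of 2 it recovered 78% for E7.75 against E7.25 epiblast, 98% for PGC against epiblast, 76% for E9.5 PGC against E7.75 epiblast, 79%, 67% and 69% for the successive PGC steps up to E12.5, 82% for E15.5 against E12.5, 69% for the sexes at E15.5, 71% for the sexes in epiblast and 34% for the difference between these. Of genes changed by 1 it recovered 81% for PGC against epiblast, 5% for the difference between the sex differences and 24% to 46% in the other comparisons. Unchanged genes made up 1% to 11.4% of the simulated calls and exceeded 5% in 6 comparisons: 11.4% between the epiblast days, 9.84% for E9.5 PGC against E7.75 epiblast, 8.70% for E15.5 against E12.5, 7.55% for the sexes at E15.5, 6.25% for the sexes in epiblast and 7.14% for the difference between these. More than 5% of the calls in these comparisons can thus be false, small changes can be missed, and genes that did not pass are not shown to be unchanged. Each comparison was simulated only once, with normal noise that had the same spread for a gene in every library. The lower depth and zeros of E10.5 and E11.5 and an unequal spread between groups were not simulated. The rates therefore need not hold for the real data.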

Results

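Messenger RNA was measured in 18 libraries from rat embryos of a Wistar strain that carry Prdm14-Venus, a fluorescent protein reporter of Prdm14, which encodes a transcriptional regulator of the germ line. Of these, 6 libraries came from epiblast, the pluripotent layer that gives rise to the embryo proper and to the germ line. These were 3 libraries at embryonic day (E) 7.25 and 3 at E7.75, on each day 2 labelled male and 1 labelled female. The other 12 came from primordial germ cells (PGC), the embryonic precursors of sperm and eggs, with 2 libraries each at E9.5, E10.5, E11.5 and E12.5, whose sex was not labelled, and 2 male and 2 female libraries at E15.5. Values were RPKM, read numbers scaled to gene length in kilobases and to the mapped reads of the library. Depth was estimated from the most common ratio of low values between libraries. It lay between 82.6% and 120.9% of that of the E7.75 female library in 14 libraries. In the 4 libraries of E10.5 and E11.5 it was 20.7% to 23.0%, so that low genes can be less precise there, which was not measured. The median absolute log2 difference between replicates was 0.335 at E10.5 but 0.233 at E11.5. Between 10701 and 12076 genes reached 1 RPKM in a library. Replicates of a group correlated at r = 0.934 to 0.965 across genes, which are not independent replicates.

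Some genes that nearly every cell expresses were listed at or near 0. Fau was 0 in all 18 libraries, Hprt1 was 0 in 11, and Gapdh had a median of 1.02 RPKM, whereas Actb ranged from 2287 to 6076 RPKM. A value of 0 is therefore given only as listed, with each library's value. Fold changes were differences of log2(RPKM + 1), which understates the change of low genes, and folds in words are ratios of mean RPKM. Errors are SD for RPKM and SE for log2 fold changes. Since all libraries share the estimate of the spread, genes listed at or near 0 in several groups, such as Stra8, draw it partly from libraries without variation. The SEs and p-values of such genes can be too small. Where no count adjusted over the list alone is given beside a gene list, it equalled the count over all genes. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

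**Figure D1:**
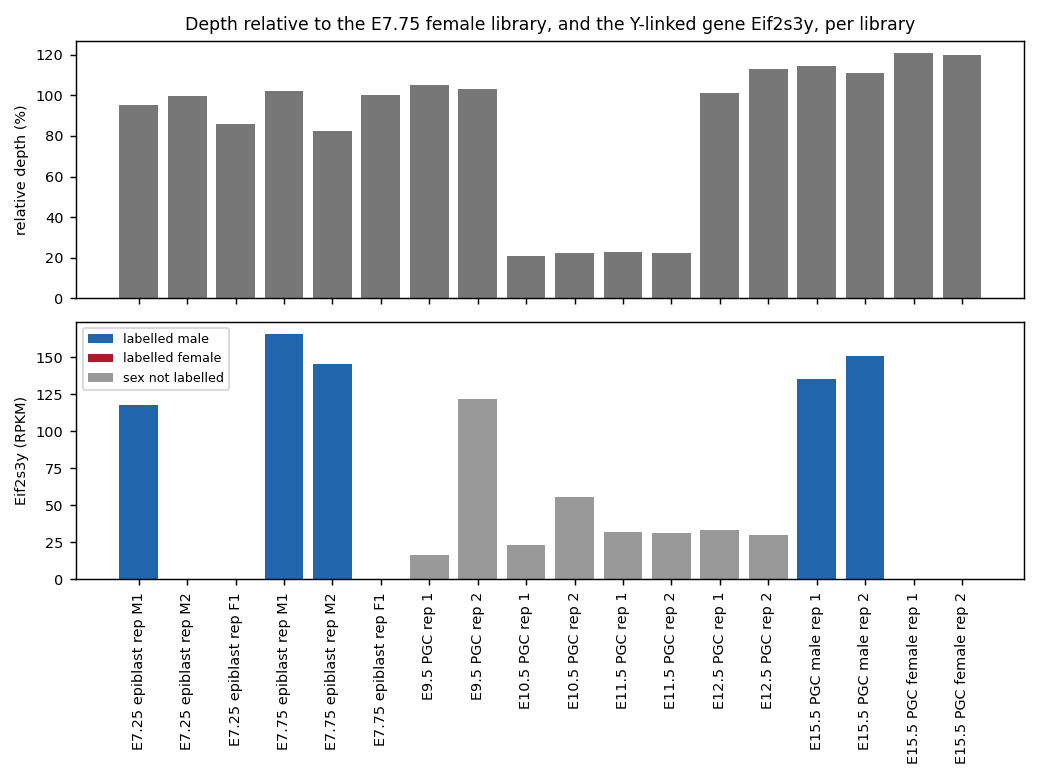
Upper bars give the depth of each of the 18 libraries relative to the E7.75 female library, in percent, and lower bars the RPKM of the Y-linked gene Eif2s3y, coloured by labelled sex. The 4 libraries of E10.5 and E11.5 stand at 20.7% to 23.0%, and the library labelled male replicate 2 at E7.25 has no Eif2s3y bar because it is listed at 0, while the 5 other male-labelled libraries lie between 117.6 and 165.8 RPKM.

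The number of genes that differed was very uneven between comparisons. Of 14865 tested genes, 8694 passed between all PGC and all epiblast libraries and 4443 between E10.5 and E9.5 PGC, against 40 between the 2 epiblast days and 9 between the sexes in epiblast (limma, Benjamini-Hochberg adjusted). Among 10 germ line and pluripotency genes fixed in advance (Prdm14, Prdm1, Tfap2c, Dppa3, Nanos3, Pou5f1, Nanog, Sox2, Dazl and Ddx4), 9 were higher and 1 lower in PGC than in epiblast. Of these, 5 were higher and 2 lower at E9.5 than in E7.75 epiblast, 3, 1 and 3 were higher and 0 lower at the steps to E10.5, E11.5 and E12.5, 2 were higher and 4 lower at E15.5 than at E12.5, and 1 was higher in female than in male PGC. None passed between the epiblast days, between the sexes in epiblast or in the test of the difference between the sex differences.

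**Figure D2:**
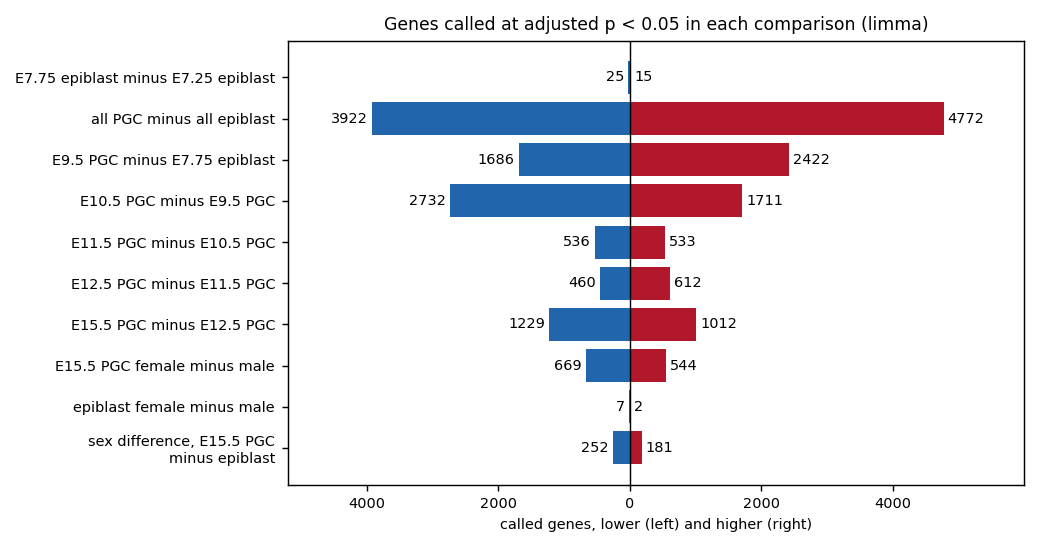
Bars give, for each of the 10 comparisons, the number of genes higher (right, red) and lower (left, blue) in the first group named, at an adjusted p under 0.05. PGC against epiblast has the longest bars, with 4772 higher and 3922 lower genes, and the sexes in epiblast the shortest, with 2 and 7.

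Epiblast was compared between E7.75 and E7.25 to see what changed there before the first PGC were sampled. Id1 and Id2, which encode inhibitors of basic helix-loop-helix factors and are targets of BMP signalling, fell. Id1 was 3.74-fold lower at E7.75, with 60.4 ± 20 against 226 ± 21.7 RPKM (n = 3 and 3; log2 fold change -1.94 ± 0.23, limma adjusted p = 0.00292), and Id2 was 3.26-fold lower. Lypd1 fell 6.70-fold, from 161 ± 37.7 to 24.1 ± 8.97 RPKM. Foxb1, a forkhead factor of the early nervous system, rose from 0.299 ± 0.482 to 7.88 ± 2.55 RPKM. Tmsb4x, the actin-binding thymosin beta 4, rose from 531 ± 15.6 to 1010 ± 86.2 RPKM.

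Of all tested genes, 15 rose and 25 fell between the epiblast days, and 28 of these 40 had a log2 fold change of at least 1 in size; 1300 genes had an unadjusted p under 0.05, where chance alone gives 743. The largest rise was that of the ribosomal protein gene Rpl30 (80.3-fold, log2 fold change 5.42 ± 0.33), which is uncertain because near-identical copies can share its reads. C1ql2 (1.84 ± 0.32) and Mettl23 (1.21 ± 0.19) also rose, and Tuba3b (-2.10 ± 0.25), Acta1 (-2.05 ± 0.38) and Hsf2bp (-1.39 ± 0.25) fell. Values of Pou5f1, the pluripotency factor Oct4, were 620 ± 84.4 at E7.75 and 447 ± 329 RPKM at E7.25, which did not pass (adjusted p = 0.605 by limma), but passed without the E7.25 library labelled male replicate 1 (1.26, adjusted p = 0.0115). Sox2 (adjusted p = 0.319) and Id3 (-0.56 ± 0.12, adjusted p = 0.104) did not pass either, and Id3 passed without the E7.75 female library (-0.69, adjusted p = 0.0344). None of the 29 gene lists passed with an estimated correlation between genes. Among 22 BMP and SMAD response genes 0 rose, 2 fell and 20 did not pass (0 and 4 adjusted over the list alone; adjusted p = 0.0510 with an estimated correlation). Among 31 gonadal germ cell and piRNA genes 0 rose and 1 fell (0 and 5 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation). No member of the lists for glycolysis (21 genes, adjusted p = 0.112 with an estimated correlation) or neural ectoderm (6 genes, 1 higher adjusted over the list alone, adjusted p = 0.373 with an estimated correlation) passed; these 4 lists passed with the preset correlation, and the first 3 also with fry, as did fetal oocyte genes (adjusted p = 0.129 with an estimated correlation). The number of genes that passed was 16 without the E7.25 female library, 23 without E7.25 male replicate 2, 18 and 23 without E7.75 male replicates 1 and 2, 21 without either E11.5 library, 18 without either E12.5 library and 9 with the 6 epiblast libraries alone. In such leave-outs C1ql2, Acta1, Hsf2bp, Mettl23 and Tmsb4x no longer passed (Mettl23, adjusted p up to 0.0821), and with a pseudocount of 0.1 neither Foxb1 (adjusted p = 0.0883) nor Lypd1 (adjusted p = 0.345) did. With the 6 epiblast libraries alone 10 of the 11 named calls ended, among them Id1 (adjusted p = 0.169), Id2 (0.111), Lypd1, Foxb1 (both 0.142), Tmsb4x (0.0595) and Tuba3b (0.180), and only that of Rpl30 remained.

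PGC of all ages were compared with epiblast of both days to describe the germ cell programme as a whole. Tfap2c, a factor required for PGC, rose from 0.123 ± 0.255 RPKM in epiblast to 295 ± 74.3 RPKM in PGC (n = 6 and 12; log2 fold change 8.02 ± 0.11, limma adjusted p = 2.97e-15). Prdm1, the repressor Blimp1, rose from 0.0806 to 23.8 ± 7.35 RPKM, Nanos3 from 1.24 to 99.2 ± 40.0 RPKM, and the reporter's gene Prdm14 from 0.185 to 9.02 ± 4.27 RPKM. The de novo DNA methyltransferase genes fell, Dnmt3b 97.3-fold from 1110 ± 148 to 11.4 ± 6.12 RPKM (-6.63 ± 0.20, adjusted p = 7.14e-12), Dnmt3a 25.9-fold, and the cofactor gene Dnmt3l from 21 ± 3.01 to 0.0739 RPKM. Pou5f1 fell 2.51-fold, from 533 ± 235 to 213 ± 80.6 RPKM.

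Of the 17 PGC specification and identity genes, 14 rose, 2 fell and 1 did not pass (the same counts adjusted over the list alone; adjusted p = 0.0213). Kit, the receptor that PGC need to survive and migrate, rose 13.4-fold, whereas Lin28a fell from 404 ± 31.7 to 79.4 ± 45.2 RPKM and Dppa4 by 2.58 on the log2 scale. Dppa3, or Stella, was listed at 0 in all 6 epiblast libraries and passed (2.72 ± 0.49, adjusted p = 0.000258), but its mean over PGC rests on E12.5 (83.7 ± 2.84 RPKM), female E15.5 PGC (61.6 ± 17.2 RPKM) and 1 E9.5 library (31.3 RPKM), and it was at most 0.537 RPKM in the 7 other PGC libraries. Nanog (2.71 ± 0.33) and Sox2 (1.51 ± 0.14) rose, and Tdgf1, the NODAL co-receptor, fell from 760 ± 301 to 14.5 ± 17.0 RPKM. Gbx2 (4.73 ± 0.31) and Nr5a2 (3.33 ± 0.17) rose. Of 16 formative and primed epiblast genes 3 rose and 10 fell (4 and 10 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation).

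Germ cell genes were higher in PGC. Of 31 gonadal germ cell and piRNA genes 24 rose and 1 fell (adjusted p = 0.00696), of 27 meiosis genes 22 rose and 0 fell (adjusted p = 0.00696), of 19 fetal oocyte genes 14 rose and 1 fell (adjusted p = 0.00696) and of 24 fetal male germ cell genes 14 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 0.0365, camera). The RNA-binding protein gene Dazl rose from 0.634 to 412 ± 449 RPKM and the RNA helicase gene Ddx4, or Vasa, from 14.2 to 145 ± 159 RPKM, with SDs as large as the means. Stk31 (4.25 ± 0.21), Tex14 (3.57 ± 0.18) and Tex12 (2.99 ± 0.22) rose. These are means over all ages: at E9.5 Dazl (0.177 RPKM), Ddx4 (1.25), Stk31 (0.0896) and Tex12 (0.771) were below their epiblast means, as was Ddx4 at E10.5 (8.43).

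Genes of BMP signalling and the embryonic trunk were also higher in PGC, as means over all ages. Of 22 BMP and SMAD response genes 18 rose and 1 fell (adjusted p = 0.00619, camera), among them Msx2 (5.30 ± 0.16), Msx1 (3.77 ± 0.23), Bmp7 (4.36 ± 0.19) and Smad6 (3.92 ± 0.34), and Bmp4 rose 14.9-fold. Msx1 varied with age, from 384 RPKM at E9.5 to 1.83 RPKM at E11.5, which is below its epiblast mean of 2.73 RPKM. Of 20 Hox genes 19 rose and 0 fell (adjusted p = 0.00696), among them Hoxb1 (1.91 ± 0.36) and Hoxd8 (1.79 ± 0.18), which was listed at 0 in every epiblast library. Of 14 extraembryonic mesoderm and allantois genes, markers of tissue that lies next to early PGC, 11 rose and 0 fell (adjusted p = 0.017, camera). These 3 lists varied with age as well. At E12.5 against E9.5, 11 of 22 BMP, 16 of 20 Hox and 11 of 14 extraembryonic mesoderm genes fell and 0 rose (medians -1.51, -2.69 and -2.51). Of 26 primitive streak and mesoderm genes 15 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation), and Eomes fell (-3.87 ± 0.18).

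Glycolysis genes were lower in PGC: of 21, 1 rose and 18 fell (adjusted p = 0.00411, camera). Slc16a3, the lactate exporter MCT4, fell 9.95-fold, and Pdk1, which restrains the oxidation of pyruvate in mitochondria, fell 8.50-fold. The lactate dehydrogenase gene Ldhb rose 3.31-fold, from 200 ± 27.6 to 664 ± 333 RPKM. Of 23 dissociation and heat stress genes, a sign of handling as well as of signalling, 16 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 0.015). Fos rose from 1.51 to 213 ± 185 RPKM and Hspb1 by 5.34 ± 0.22. Among the largest rises were those of Tapbp (5.92 ± 0.21), which encodes the peptide-loading protein tapasin, Parp12 (5.74 ± 0.17) and the immune proteasome gene Psmb8 (5.73 ± 0.10), the latter 2 listed at 0 in all 6 epiblast libraries. Tspan8 rose 117-fold and Gfra3 by 5.49 ± 0.10. The largest falls included the metallothionein genes Mt2A (-6.53 ± 0.17), Mt1m and Mt1, which are near-identical and uncertain, and the gap junction gene Gja1 (-6.38 ± 0.25). Among other named genes Peg3 (3.28 ± 0.14) and Cenpa (2.84 ± 0.09) rose, and Ccnd1 (-4.25 ± 0.14) and Snrpn (-3.99 ± 0.45) fell.

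In all, 4772 genes were higher and 3922 lower in PGC, 3626 of them by a log2 fold change of at least 1. The SEs and p-values of this comparison rest on the spread within the 8 groups, not on that between ages. With PGC and epiblast fitted as 2 groups, 5997 genes passed. None of the 48 genes named here lost its call when any 1 library was left out. With only the PGC of E9.5 to E12.5 on the germ cell side, Ddx4 no longer passed (0.44, adjusted p = 0.192 by limma).

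**Figure D3:**
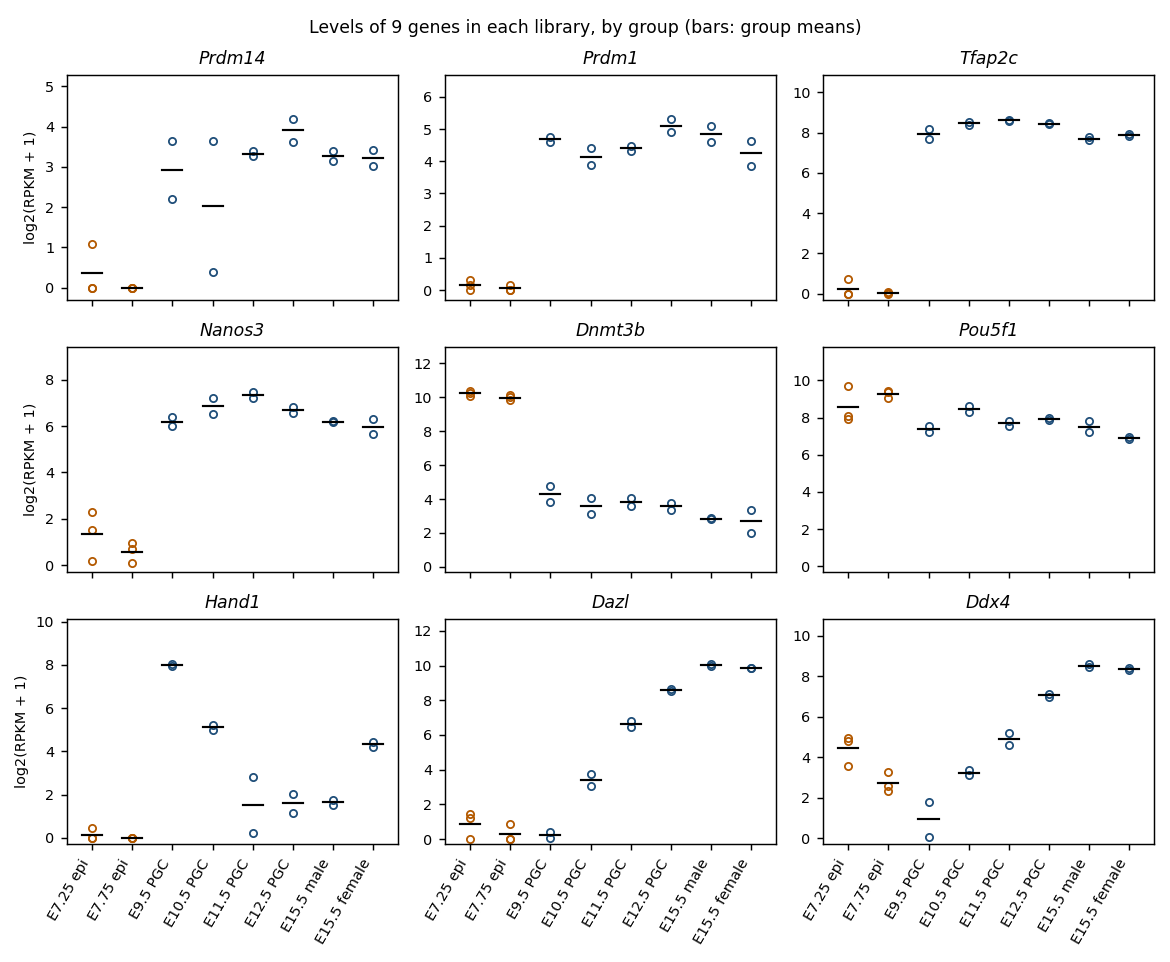
Each panel plots log2(RPKM + 1) of 1 gene against the 8 groups in order of age, with a circle per library and a bar at the group mean. Tfap2c, Prdm1 and Nanos3 are near 0 in epiblast and high in every PGC group, Dnmt3b falls 51.1-fold between E7.75 epiblast and E9.5 PGC, Hand1 peaks at 261 and 245 RPKM at E9.5, and Dazl and Ddx4 climb from E10.5 to E15.5.

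The youngest PGC, at E9.5, were compared with E7.75 epiblast to ask what distinguishes them from the layer of their origin. Tfap2c rose from 0.0336 to 247 ± 57.1 RPKM (n = 3 and 2; log2 fold change 7.89 ± 0.20, limma adjusted p = 1.56e-11), Nanos3 from 0.530 to 73.3 ± 15.3 RPKM and Prdm1 from 0.0398 to 24.8 ± 1.98 RPKM. BMP targets of mesoderm rose: Msx1 141-fold to 384 ± 9.10 RPKM, Msx2 340-fold to 229 ± 27.6 RPKM, and Hand1 from a listed 0 in all 3 epiblast libraries to 261 and 245 RPKM. Dnmt3b fell 51.1-fold, from 1013 ± 94.4 to 19.8 ± 8.99 RPKM (-5.67 ± 0.37, adjusted p = 1.12e-07), and Pou5f1 fell 3.68-fold, from 620 ± 84.4 to 168 ± 29.5 RPKM.

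Of 22 BMP and SMAD response genes 18 rose and 0 fell (adjusted p = 0.000185, camera; median log2 fold change 3.40). Of 20 Hox genes 19 rose and 0 fell (adjusted p = 9.29e-05; median 2.99); Hoxb6 (4.95 ± 0.35) and Hoxb2 (4.44 ± 0.50) were listed at 0 in E7.75 epiblast. Of 26 primitive streak and mesoderm genes 21 rose and 2 fell (adjusted p = 0.00511). Cdx1 was listed at 0 in E7.75 epiblast and at 42.8 and 151.6 RPKM at E9.5, Wnt5a rose by 5.80 ± 0.34, and Eomes (-3.49 ± 0.33) and Wnt3 (-1.77 ± 0.45) fell. Of 17 PGC specification and identity genes 11 rose and 2 fell (adjusted p = 0.0328). Prdm14 stood at 11.5 and 3.64 RPKM at E9.5 against a listed 0, and Dppa3 at 0.106 and 31.3 RPKM against a listed 0. Of 27 imprinted genes 13 rose and 2 fell (15 and 3 adjusted over the list alone; adjusted p = 0.00511), with Phlda2 281-fold higher at 330 ± 140 RPKM and Cdkn1c 127-fold higher at 1037 ± 373 RPKM.

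Markers of other embryonic cells were high in the E9.5 libraries. Of 14 extraembryonic mesoderm and allantois genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.000332, camera), and of 18 mesenchyme and matrix genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0105), with Prrx2 at 118 ± 2.63 against 1.79 RPKM and Twist1 up by 4.55 ± 0.49. Of 12 endothelial genes 6 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). Etv2, a factor of the blood and vessel lineage, rose from 1.62 to 69.8 ± 5.71 RPKM. The replicates differed here: in replicates 1 and 2, Kdr was 55.2 and 25.3, Tal1 23.4 and 2.82, and the endothelial gene Cldn5 27.4 and 0 RPKM. Hand1 and Msx1 were alike in both. Of the gut epithelial genes, Krt19 rose (5.22 ± 0.54) and Epcam fell (-1.07 ± 0.11).

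Glycolysis genes fell: of 21, 2 rose and 14 fell (adjusted p = 0.00511, camera, but 0.145 under quantile normalization). Pgk1 fell 2.88-fold, from 1532 ± 113 to 532 ± 53.3 RPKM, and Pdk1 by 1.82 on the log2 scale, while Ldhb rose (1.30 ± 0.14). Of 20 adhesion and migration genes 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). The E-cadherin gene Cdh1 fell 4.74-fold, the P-cadherin gene Cdh3 rose by 3.50 ± 0.28, and the chemokine receptor gene Cxcr4 rose by 3.31 ± 0.52. Of 16 formative and primed epiblast genes 2 rose and 8 fell (adjusted p = 0.159 with an estimated correlation), with Dnmt3a at -4.55 ± 0.29, and the pluripotency gene Utf1 fell 4.36-fold. Of 31 gonadal germ cell and piRNA genes 2 rose and 5 fell (adjusted p = 0.165 with an estimated correlation), and Ddx4 fell from 5.89 to 1.25 RPKM. Of 19 fetal oocyte genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0167), and of 23 stress genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.0305), with Fos (5.19 ± 0.42) and Hspb1 (6.61 ± 0.41) higher. The DNA demethylation gene Gadd45g rose by 4.2 ± 0.73. Of 10 mitochondrially encoded genes 0 rose and 7 fell (adjusted p = 0.225 with an estimated correlation). Tapbp rose (6.40 ± 0.39), and the largest falls were those of Tdgf1 (-7.29 ± 0.67), the amino acid transporter gene Slc7a3 (70.8-fold lower), Sncb (143-fold lower) and Mt2A (-5.44 ± 0.31). Lin28a also fell (-1.15 ± 0.14). Nanog (37.3 ± 0.436 against 20.6 ± 16.8 RPKM, adjusted p = 0.185), Sox2 (0.17 ± 0.26) and Sall4 (-0.09 ± 0.24, 232 ± 109 against 237 ± 46.2 RPKM) did not pass. The signs of Sox2 and Sall4 changed with the scaling or with single libraries.

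In all, 2422 genes were higher and 1686 lower in E9.5 PGC, 2651 of them by a log2 fold change of at least 1. Quantile normalization gave 2028 and 2173, so that the share of higher genes moved from 59.0% to 48.3%. Rescaling to TPM gave 2993 and 1381, a share of 68.4%, and moved the median of all genes by 0.11. With only the 5 libraries compared 2204 genes passed, and Dppa3, Wnt3, Tal1 and Ddx4 did not. Prdm14 no longer passed without E9.5 replicate 1 (2.22, adjusted p = 0.0855 by limma), nor Wnt3 (adjusted p = 0.0699). Without E9.5 replicate 2, Dppa3 (0.15, adjusted p = 0.832) and Ddx4 (-0.93, adjusted p = 0.171) no longer passed. Nanog passed without E7.75 male replicate 2 (1.73, adjusted p = 0.0340).

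Between E9.5 and E10.5 PGC, mesodermal genes fell and germ cell genes rose. Msx1 fell 7.78-fold, from 384 ± 9.10 to 49.4 ± 1.90 RPKM (n = 2 and 2; log2 fold change -2.94 ± 0.46, limma adjusted p = 0.000335), Hand1 fell 7.54-fold and Prrx2 41.7-fold. Etv2 and Kdr were listed at 0 in both E10.5 libraries, against 73.9 and 65.8 RPKM for Etv2 at E9.5. Utf1 rose 6.90-fold, from 278 ± 6.67 to 1921 ± 85.2 RPKM, Sox2 3.36-fold to 153 ± 6.31 RPKM, and Dazl 56.0-fold to 9.93 ± 3.71 RPKM. The 2 E10.5 libraries had 20.7% and 22.1% of the reference depth.

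Of 31 gonadal germ cell and piRNA genes 15 rose and 1 fell (adjusted p = 0.0243, camera); Ddx4 rose 6.73-fold, from 1.25 ± 1.71 to 8.43 ± 1.06 RPKM, and Fkbp6 by 3.14 ± 0.59. Rhox5, of the PGC list, rose 10.5-fold to 295 ± 26.1 RPKM. Of 27 meiosis genes 6 rose and 1 fell (adjusted p = 0.153 with an estimated correlation), among them Tex12 (2.97 ± 0.45) and Tex14 (2.55 ± 0.35). Of 39 oxidative phosphorylation genes 30 rose and 0 fell (adjusted p = 0.0473, and 0.0563 with the replicate number as a block), with Uqcrq up 3.49-fold and Cox5a 3.31-fold, and of 10 mitochondrially encoded genes 10 rose (adjusted p = 0.094 with an estimated correlation). Of 21 glycolysis genes 1 rose and 14 fell (1 and 15 adjusted over the list alone; adjusted p = 0.0243), with Slc16a3 (-2.02 ± 0.34) and Pdk1 (-1.71 ± 0.30) lower and Ldhb higher (1.10 ± 0.15). Of 17 pluripotency genes 3 rose and 2 fell (adjusted p = 0.171 with an estimated correlation). Tcl1a rose 29.2-fold, and Nodal from 1.15 to 24.2 ± 6.46 RPKM. Pou5f1 (353 ± 49.7 against 168 ± 29.5 RPKM, adjusted p = 0.0689) and Tfap2c (350 ± 22.2 against 247 ± 57.1 RPKM, adjusted p = 0.0878) did not pass, but Pou5f1 passed without E7.25 male replicate 1 (adjusted p = 0.00166) or 2 (adjusted p = 0.0480), and Tfap2c without E9.5 replicate 2 (adjusted p = 0.0412) or E7.25 male replicate 2 (adjusted p = 0.0231).

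Lists of trunk and mesodermal genes fell. Of 20 Hox genes 1 rose and 17 fell (adjusted p = 0.00262, camera), with Hoxb6 listed at 0 in both E10.5 libraries. Of 26 primitive streak and mesoderm genes 0 rose and 18 fell (0 and 21 adjusted over the list alone; adjusted p = 0.0139), of 14 extraembryonic mesoderm genes 0 rose and 11 fell (adjusted p = 0.00497), and of 18 mesenchyme genes 0 rose and 10 fell (0 and 12 adjusted over the list alone; adjusted p = 0.0139). Foxf1 and Pitx1 were listed at 0 in both E10.5 libraries, and Twist1 (-4.39 ± 0.54) and Snai1 (-5.51 ± 0.58) fell. Of 17 hindgut genes 1 rose and 8 fell (adjusted p = 0.039), with Krt8 20.8-fold lower. Of 12 endothelial genes 0 rose and 8 fell (0 and 9 adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), of 22 endoderm genes 0 rose and 5 fell (adjusted p = 0.381 with an estimated correlation), and of 20 adhesion genes 0 rose and 7 fell (adjusted p = 0.109 with an estimated correlation). Of 27 imprinted genes 0 rose and 17 fell (0 and 18 adjusted over the list alone; adjusted p = 0.00314), among them Cdkn1c, 110-fold lower at 9.45 ± 2.68 RPKM, Mest, 25.7-fold lower, and Phlda2 (-2.79 ± 0.56). Of 22 BMP genes 1 rose and 9 fell (adjusted p = 0.0479, and 0.0646 with the replicate number as a block); Id3 rose (0.81 ± 0.15) and Bmp4 did not pass (0.40 ± 0.32). Other large changes were the falls of Gja1 (380-fold), Ccnd2 (16.9-fold), Ccnd1 (15.7-fold) and Lin28a (4.91-fold), and the rises of Rpl39l (27.7-fold), Ifitm1 (9.14-fold) and Birc5 (3.14-fold), of Pramef12 (4.39 ± 0.41) and of Tex19.2 (4.33 ± 0.27). Rpl39l and Ifitm1 belong to families of similar copies and are uncertain.

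In all, 1711 genes were higher and 2732 lower at E10.5, 3060 of them by a log2 fold change of at least 1, and the share of higher genes depended on the scaling: 38.5% as deposited, 21.6% on the TPM scale, with a median shift of -0.25, and 51.7% after quantile normalization, with a shift of 0.19. None of the 39 named calls ended without any 1 library, but none remained when the 4 libraries were fitted alone (0 genes passed). Under quantile normalization Id3 (0.20, adjusted p = 0.296 by limma) and Ldhb (0.49, adjusted p = 0.0571) no longer passed, and with a pseudocount of 0.1 neither did Hand1 (adjusted p = 0.0643).

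**Figure D4:**
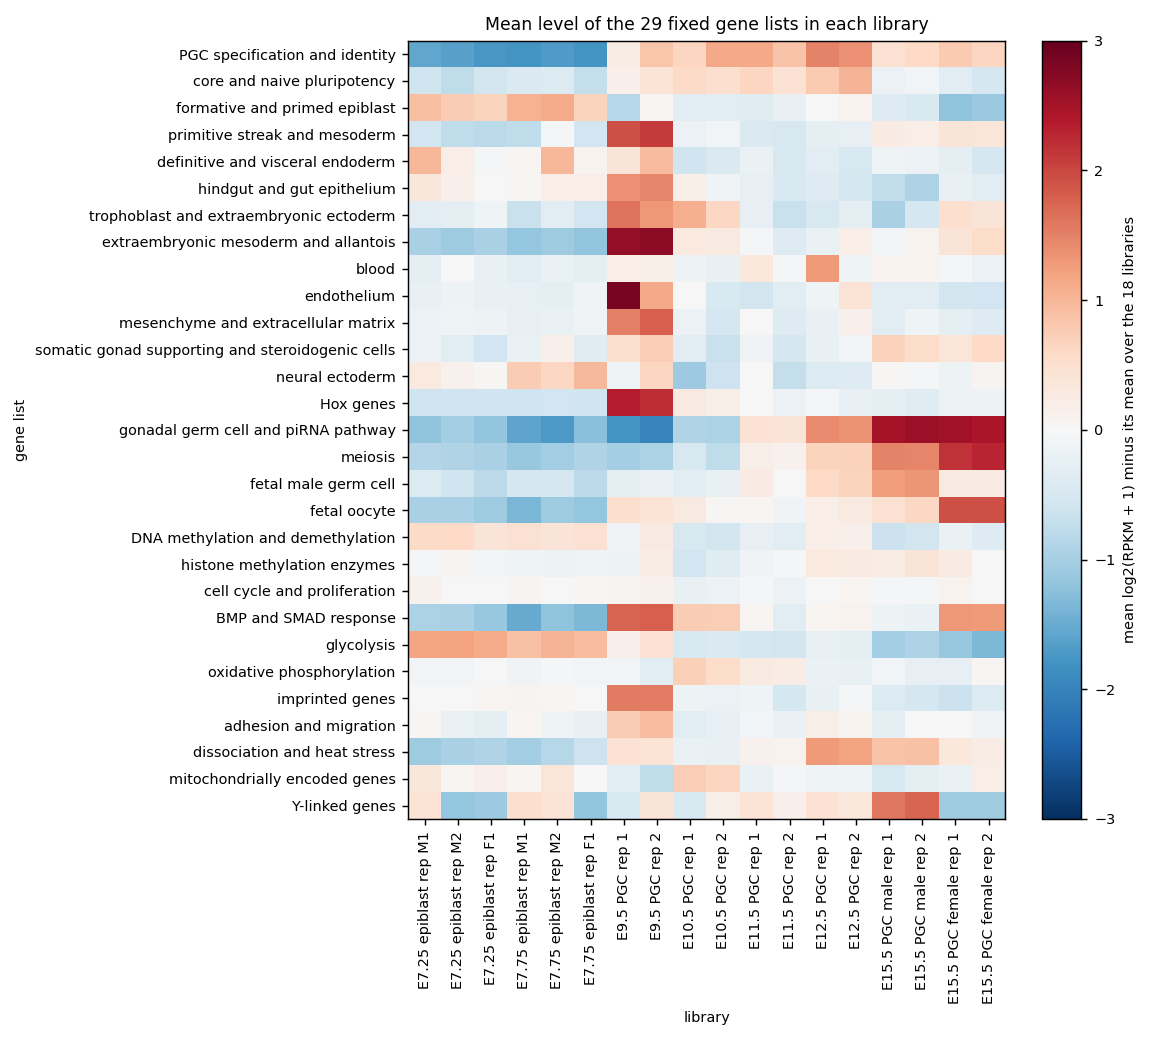
The heat map gives, for each of the 29 fixed gene lists (lines) and 18 libraries (columns, in order of age), the mean log2(RPKM + 1) of the list minus its mean over the libraries. Lists of mesoderm, Hox and mesenchyme genes are highest in the 2 libraries of E9.5, glycolysis is highest in the 6 epiblast libraries, the germ cell and meiosis lists are highest at E15.5, and the fetal oocyte list is highest in the 2 female libraries of E15.5.

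Between E10.5 and E11.5 PGC, germ cell genes rose further and BMP targets fell. Dazl rose 9.92-fold, from 9.93 ± 3.71 to 98.5 ± 16.1 RPKM (n = 2 and 2; log2 fold change 3.22 ± 0.41, limma adjusted p = 0.000679), and Mael, a piRNA pathway gene, was listed at 0 in both E10.5 libraries and at 7.04 and 6.84 RPKM at E11.5. Tet1, which encodes an enzyme that oxidises 5-methylcytosine, rose 6.38-fold to 10.9 ± 1.67 RPKM. Msx1 fell 27.0-fold to 1.83 ± 0.751 RPKM, and Phlda2 fell 269-fold.

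Of 31 gonadal germ cell and piRNA genes 12 rose and 0 fell (18 and 1 adjusted over the list alone; adjusted p = 0.00989, camera), and of 27 meiosis genes 7 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0893 with an estimated correlation), among them Tex12 (2.43 ± 0.45); Tex19.1 rose by 2.82 ± 0.63. Of 22 BMP genes 0 rose and 8 fell (0 and 9 adjusted over the list alone; adjusted p = 0.0132), with Id1 3.49-fold lower; Bmp4 did not pass (178 ± 4.18 against 199 ± 2.46 RPKM, adjusted p = 0.870). Hand1 fell 11.1-fold, Cdx1 by 2.90 and the trophoblast gene Cdx2 by 3.06 on the log2 scale; of 11 trophoblast genes 0 rose and 4 fell (0 and 5 adjusted over the list alone; adjusted p = 0.229 with an estimated correlation). Of 33 histone methylation enzyme genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.333 with an estimated correlation). Of 39 oxidative phosphorylation genes 0 rose and 12 fell (0 and 20 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), and of 10 mitochondrially encoded genes 0 rose and 6 fell (0 and 10 adjusted over the list alone; adjusted p = 0.229 with an estimated correlation), with Mt-co1 at 633 ± 51.6 against 1352 ± 79.2 RPKM. Il33 was listed at 0 in both E10.5 libraries and at 23.8 and 29.7 RPKM at E11.5. Snrpn (3.34 ± 0.90), Tdgf1 (2.58 ± 0.73), Fos (2.44 ± 0.46), Uhrf1 (1.18 ± 0.29) and Lin28a (1.13 ± 0.16) rose, and Hspb1 fell (-2.05 ± 0.45).

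In all, 533 genes were higher and 536 lower at E11.5, 632 of the 1069 by a log2 fold change of at least 1. Rescaling to TPM gave 1093 and 291, a share of 79.0% in place of 49.9%, with a median shift of 0.19. The number of genes was 543 without E10.5 replicate 1, 399 and 347 without E11.5 replicates 1 and 2, and 56 with the 4 libraries alone, where none of the 19 named genes passed. In leave-outs Tex19.1 (adjusted p up to 0.109 by limma), Uhrf1 (up to 0.174), Hspb1, Snrpn, Tdgf1, Tex12 (0.0592 without E11.5 replicate 2) and Fos (0.0581 without E11.5 replicate 2) no longer passed, nor did Mt-co1 under quantile normalization (-0.55, adjusted p = 0.0915).

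Between E11.5 and E12.5 PGC, Dppa3 rose 170-fold, from 0.491 ± 0.00917 to 83.7 ± 2.84 RPKM (n = 2 and 2; log2 fold change 5.83 ± 0.97, limma adjusted p = 0.00341), although near-identical copies make this gene uncertain. The germ cell gene Tex15 rose 4.68-fold to 36.8 ± 5.81 RPKM, Dazl 3.87-fold to 381 ± 17.6 RPKM and Ddx4 4.51-fold to 132 ± 8.76 RPKM. Kdm3a, a histone H3K9 demethylase gene, rose 3.06-fold and the pluripotency factor gene Klf4 14.4-fold. Penk, which encodes proenkephalin, fell 10.5-fold.

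Of 31 gonadal germ cell and piRNA genes 7 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.0459, camera, and 0.0554 with the replicate number as a block), among them Mov10l1 (1.42 ± 0.32). Of 23 dissociation and heat stress genes 10 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 0.00268); Fos rose 5.01-fold to 503 ± 30.8 RPKM, and Atf3, listed at 0 in both E11.5 libraries, stood at 2.66 and 4.66 RPKM. Of 39 oxidative phosphorylation genes 0 rose and 14 fell (0 and 21 adjusted over the list alone; adjusted p = 0.254 with an estimated correlation), with Cox5b 2.63-fold lower and Uqcrq at -1.16 ± 0.21. Of 21 glycolysis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; adjusted p = 0.254 with an estimated correlation). Lefty2 (3.59 ± 0.76), Mest (3.16 ± 0.64), Msx1 (2.50 ± 0.46), Dnmt3a (1.37 ± 0.32), the Polycomb gene Suz12 (1.18 ± 0.27) and Mki67 (1.03 ± 0.19) rose, and Plk5 (-2.74 ± 0.59), Nr0b1 (-2.58 ± 0.39) and Ifitm1 (-0.80 ± 0.22) fell. Globin transcripts differed between the E12.5 replicates: Hbz was 226.1 and 1.07 and Hbe1 97.4 and 0 RPKM in replicates 1 and 2. Hbz did not pass (adjusted p = 0.0655 by limma), but did without replicate 2 (7.83, adjusted p = 3.08e-05).

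In all, 612 genes were higher and 460 lower at E12.5, 578 of the 1072 by a log2 fold change of at least 1. The balance depended on the scaling, with 459 higher and 501 lower under the median of ratios and 618 and 665 under quantile normalization. The number was 332 and 487 without E11.5 replicates 1 and 2, 364 and 219 without E12.5 replicates 1 and 2, and 0 with the 4 libraries alone. The calls of Dppa3, Tex15, Kdm3a, Klf4, Penk, Nr0b1 and Cox5b held without any 1 library. In at least 1 leave-out Lefty2, Mest, Ddx4, Dazl (adjusted p up to 0.0958 by limma), Mov10l1, Dnmt3a, Suz12, Mki67, Fos, Atf3, Msx1, Uqcrq, Ifitm1 and Plk5 no longer passed.

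PGC at E15.5, as the mean of the male and female groups, were compared with E12.5 to follow the oldest stage sampled. The spread between the sexes is not part of the p-values of this comparison. Ddx43, an RNA helicase gene of the germ line, rose 23.1-fold, from 3.43 ± 1.58 to 79.3 ± 25.1 RPKM (n = 2 and 4; log2 fold change 4.17 ± 0.27, limma adjusted p = 4.47e-07), and Dazl rose 2.60-fold to 991 ± 63.7 RPKM. Pluripotency genes fell: Nanog 3.87-fold to 30.1 ± 10.9 RPKM, Sox2 2.04-fold, and Tdgf1 7.95-fold. Ldha fell 7.87-fold, from 269 ± 4.70 to 34.2 ± 6.16 RPKM. Il33, which had risen at E11.5, fell 106-fold, from 68.5 ± 12.2 to 0.645 ± 0.600 RPKM.

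Of 31 gonadal germ cell and piRNA genes 17 rose and 0 fell (21 and 0 adjusted over the list alone; adjusted p = 0.00417, camera), among them Tdrd5 (7.82-fold), Tex11 (2.37 ± 0.43) and Ddx4 (2.64-fold). Of 27 meiosis genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.00314). Rec8, a meiotic cohesin gene, rose by 2.70 ± 0.56, and Stra8, which marks entry into meiosis, was listed at 0 at E12.5 and in both male libraries but at 71.9 and 80.4 RPKM in the female ones. Of 19 fetal oocyte genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 0.00417), with Ooep 20.4-fold (29.1 ± 3.61 RPKM in female and 6.80 ± 1.10 in male PGC) and Zglp1 19-fold higher (134 ± 26.9 and 11.2 ± 3.33 RPKM). Of 17 pluripotency genes 1 rose and 7 fell (1 and 9 adjusted over the list alone; adjusted p = 0.0189), with Klf2 at -2.99 ± 0.59. Pou5f1 did not pass (152 ± 49.6 against 244 ± 14.6 RPKM, adjusted p = 0.214), but did without E7.25 male replicate 1 (adjusted p = 0.0136). Of 17 PGC specification genes 0 rose and 5 fell (0 and 6 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), among them Tfap2c (1.56-fold lower), Dppa3 (-3.19 ± 0.84; 61.6 ± 17.2 RPKM in female and 0.395 in male PGC, against 83.7 at E12.5) and Ifitm1 (4.32-fold lower). Of 24 DNA methylation genes 0 rose and 7 fell (0 and 10 adjusted over the list alone; adjusted p = 0.0189), with Dnmt3a at -1.99 ± 0.27.

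Of 21 glycolysis genes 0 rose and 14 fell (0 and 15 adjusted over the list alone; adjusted p = 0.0026, camera), Slc16a3 among them (-2.16 ± 0.30). Of 23 stress genes 0 rose and 7 fell (0 and 8 adjusted over the list alone; adjusted p = 0.0189), with Zfp36 (-3.01 ± 0.39) and Dusp1 (-2.40 ± 0.24). Of 22 BMP genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation): Msx1 rose (2.77 ± 0.40; 250 ± 45.1 RPKM in female and 45.2 in male PGC, against 15.1 at E12.5) and Bmp4 fell 6.49-fold. Of 26 primitive streak genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.260 with an estimated correlation), with Wnt3 (2.74 ± 0.43; 1.46 RPKM in female and 26.9 in male PGC, against 0.236 at E12.5) and Sp5 (3.31 ± 0.60) higher. Of 16 formative and primed epiblast genes 2 rose and 8 fell (3 and 10 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), with Lefty2 lower (-3.73 ± 0.66; 0.843 RPKM in female and 111 in male PGC, against 189 at E12.5). Utf1 fell as well (-0.97 ± 0.12). Of 16 somatic gonad genes, markers of cells around the germ cells, 3 rose and 0 fell (adjusted p = 0.109 with an estimated correlation), among them Dmrt1 (6.75-fold), which germ cells also express. Lmo1 (36.9-fold), Pcp4l1 (43.7-fold), Lgals9 (69.5-fold) and Cdkn1c (2.24 ± 0.43) rose, and Krt18 (12.8-fold), Sparc (8.30-fold), Peg3 (-2.07 ± 0.24), Ccnd3 (-2.04 ± 0.22) and Hbz (listed at 0 in all 4 E15.5 libraries) fell.

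In all, 1012 genes were higher and 1229 lower at E15.5, 1376 of the 2241 by a log2 fold change of at least 1, and 1003 and 884 passed without E12.5 replicates 1 and 2. Means of both sexes together combine unlike levels where the sexes differ, as they did, among others, for Dppa3, Wnt3, Lefty2, Stra8, Rec8, Tdgf1, Utf1 and Zfp36 (below). Without an E12.5 library Rec8 (2.27, adjusted p = 0.0832 by limma), Klf2 (adjusted p = 0.0616), Dppa3 (0.125), Hbz (-1.05, 0.294) and Sox2 (0.0957) no longer passed, and in leave-outs neither did Dazl (up to 0.138), Ddx4 (up to 0.240), Nanog (up to 0.214) and Tfap2c (up to 0.192).

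At E15.5 female PGC were compared with male PGC to describe how germ cells of the sexes differ. Stra8 was listed at 0 in both male libraries and at 71.9 and 80.4 RPKM in the female ones (n = 2 and 2; log2 fold change 6.27 ± 0.26, limma adjusted p = 3.52e-07), and Rec8 was 8.48-fold higher in female PGC. Targets of BMP signalling were higher in female PGC: Id1 35.6-fold, with 1073 ± 165 against 30.2 ± 1.15 RPKM, Id2 20.5-fold, with 450 ± 68.2 RPKM, and Msx2 5.73-fold. The NODAL pathway genes Lefty2 (131-fold, with 111 ± 4.64 RPKM in male PGC) and Tdgf1 (-3.36 ± 0.78) were lower in female PGC. Nanos2, a regulator of male germ cell fate, stood at 1.64 against 14.1 ± 6.28 RPKM in male PGC.

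Of 22 BMP genes 10 were higher and 0 lower in female PGC (11 and 1 adjusted over the list alone; adjusted p = 0.00842, camera), and of 19 fetal oocyte genes 11 were higher and 1 lower (11 and 3 adjusted over the list alone; adjusted p = 0.00842), with Gata2 listed at 0 in both male libraries and at 45.0 and 33.4 RPKM in the female ones, and Sohlh1 lower (-2.39 ± 0.27). The 2 lists share members, among them Id1, Id2, Msx2 and Gata2. Dppa3 was 156-fold higher in female PGC, with 61.6 ± 17.2 RPKM. Of 24 fetal male germ cell genes 1 was higher and 5 were lower (1 and 6 adjusted over the list alone; adjusted p = 0.026). Of 27 meiosis genes 4 were higher and 0 lower (adjusted p = 0.067 with an estimated correlation). Of 23 stress genes 1 was higher and 9 were lower (2 and 10 adjusted over the list alone; adjusted p = 0.0144), with Nr4a1 at -2.97 ± 0.53 and Zfp36 at -2.46 ± 0.44. Of 21 glycolysis genes 2 were higher and 5 lower (2 and 8 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation): Pdk1 was 20.8-fold higher, and Hk2 (-2.44 ± 0.34) and Aldoa (1.92-fold) were lower. Of 16 formative and primed epiblast genes 1 was higher and 3 were lower (1 and 5 adjusted over the list alone; adjusted p = 0.580 with an estimated correlation). Utf1 was 2.55-fold lower, at 421 ± 53.4 RPKM. Of 11 trophoblast genes 3 were higher and 0 lower (5 and 1 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), among them Cdx2 (2.96 ± 0.53) and Phlda2 (3.57 ± 0.50). No mitochondrially encoded gene passed (adjusted p = 0.682 with an estimated correlation). Wnt3 was 18.4-fold and the adenosine deaminase gene Ada 18.8-fold lower, and Ccnd2 was higher (3.55 ± 0.70). Dazl (939 ± 1.11 against 1042 ± 37.3 RPKM, adjusted p = 0.803) and Pou5f1 (-0.60 ± 0.41) did not pass.

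Of 7 Y-linked genes 0 were higher and 5 lower in female PGC (1 and 6 adjusted over the list alone; adjusted p = 0.0744 with an estimated correlation), the lower ones including Eif2s3y (0.0666 against 143 ± 10.9 RPKM), Uba1y (-4.46 ± 0.27) and Kdm5d (-2.99 ± 0.80). The 1 higher is the line of Ddx3y used in the list (16.3 ± 1.92 against 6.52 ± 1.44 RPKM). The other line of this symbol stood at 0.00441 against 9.62 ± 0.114 RPKM. In epiblast the line used stood at 11.4 ± 4.32 RPKM in female-labelled and 9.78 ± 0.86 RPKM in male-labelled libraries. The line used was thus not specific to males, but it is counted in the Y-linked list and its tests. The X-linked genes came from general knowledge, a list not fixed in advance: of 110, 37 were higher and 0 lower in female PGC (48 and 0 adjusted over the list alone; adjusted p = 0.00225, camera), with a median of 0.61. Emd was 4.54-fold higher, Porcn was higher by 1.82 ± 0.31, and Morf4l2 did not pass (0.28 ± 0.11).

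In all, 544 genes were higher and 669 lower in female PGC, 838 of the 1213 by a log2 fold change of at least 1; on the TPM scale there were 688 and 648, so that the balance depended on the scaling. The number was 445 and 470 without male replicates 1 and 2, 735 and 563 without female replicates 1 and 2, and 0 with the 4 libraries alone. In leave-outs Rec8 (adjusted p up to 0.157 by limma), Dppa3 (0.0640), Ccnd2 (0.0661), Tdgf1 (0.141), Eif2s3y (0.0961), Kdm5d (0.213), Nr4a1 (0.0542), Zfp36 (0.0581), Porcn (0.0507) and Nanos2 (0.0820) no longer passed.

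In epiblast the sexes were compared over both days. Eif2s3y stood at 0.0933 RPKM in female-labelled and at 107 ± 74.1 RPKM in male-labelled libraries (n = 2 and 4; log2 fold change -5.24 ± 1.36) and did not pass (limma adjusted p = 0.653). It was listed at 0 in the E7.25 library labelled male replicate 2, and without that library it passed (-6.96, adjusted p = 0.00253). Nanog (4.14 ± 4.73 against 16.3 ± 16.3 RPKM, adjusted p = 0.568), Sox2 (25.1 against 36.0 RPKM), Pou5f1 (397 ± 178 against 601 ± 251 RPKM) and Kdm5d (-1.67) did not pass.

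Only 9 genes passed between the sexes in epiblast, 2 higher and 7 lower, all of them small RNA genes, and 0 passed with small RNA genes left out. At an unadjusted p under 0.05 there were 686 genes, where chance gives 743. No list passed with an estimated correlation; formative and primed epiblast genes (adjusted p = 0.550 with an estimated correlation), endoderm (0.351), stress (0.350) and Y-linked genes (0.351; 0 higher and 1 lower adjusted over the list alone) passed with the preset correlation only. The number of genes was 3 without E7.25 male replicate 1, 2 without the E7.25 female library, 23 without E7.75 male replicate 1, 15 without E9.5 replicate 2, and 150 with the epiblast libraries alone.

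The sex difference at E15.5 was then tested directly against that in epiblast. It was larger at E15.5 for Stra8 (difference of log2 differences 6.39 ± 0.35, limma adjusted p = 3.49e-06), Gata2 (5.24 ± 0.78), Id1 (4.78 ± 0.38), Id2 (4.59 ± 0.37) and Id4 (4.40 ± 0.67), all with higher female values at E15.5. It was more negative at E15.5 for the male-high genes Lefty2 (-4.70), Ada (-4.38 ± 0.41), Wnt3 (-3.15 ± 0.67) and Utf1 (-1.26 ± 0.18). Lefty2 had 2 lines in the file, the other at -5.43 ± 0.39, and is uncertain. The female and male groups of E15.5 had 2 libraries each, those of epiblast 2 and 4.

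Of 19 fetal oocyte genes 8 had a higher and 1 a lower difference (12 and 2 adjusted over the list alone; adjusted p = 0.00649, camera; median 1.63), and of 22 BMP genes 9 and 0 (10 and 0 adjusted over the list alone; adjusted p = 0.00649; median 0.98). Of 23 stress genes 1 had a higher and 3 a lower difference (1 and 10 adjusted over the list alone; adjusted p = 0.00649; median -0.85), with Nr4a1 (-3.56 ± 0.71) and Fos (-2.36 ± 0.45). Of 110 X-linked genes 12 had a higher and 0 a lower difference (24 and 0 adjusted over the list alone; adjusted p = 0.00371; median 0.61). The lists for trophoblast (1 higher and 0 lower, 3 and 0 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation), meiosis (1 and 0; 0.152), fetal male germ cells (1 higher and 2 lower, 1 and 4 adjusted over the list alone; 0.137), mitochondrially encoded genes (0.599) and Y-linked genes (0 and 2; 0.278) passed with the preset correlation; of these, meiosis, fetal male germ cells and Y-linked genes also passed with fry, as did hindgut genes (0.429 with an estimated correlation). Pdk1 (3.51 ± 0.43), Ccnd2 (4.18 ± 0.93) and Kit (1.81 ± 0.34) had a higher and Uba1y (-4.44 ± 0.36) a lower difference.

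In all, 433 genes passed this test, 181 with a higher and 252 with a lower difference (237 and 230 on the TPM scale), and 2479 had an unadjusted p under 0.05. The number was 345 without the E7.25 library labelled male replicate 2, 162 and 222 without the E7.25 and E7.75 female libraries, 189 and 192 without E15.5 male replicates 1 and 2, and 254 and 240 without E15.5 female replicates 1 and 2. In leave-outs Kit (adjusted p up to 0.194 by limma), Ccnd2 (0.144), Lefty2 (0.103), Wnt3 (0.118), Fos (0.127) and Nr4a1 (0.0963) no longer passed, and with the compared libraries alone Kit, Wnt3, Fos and Nr4a1 did not.

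**Figure D5:**
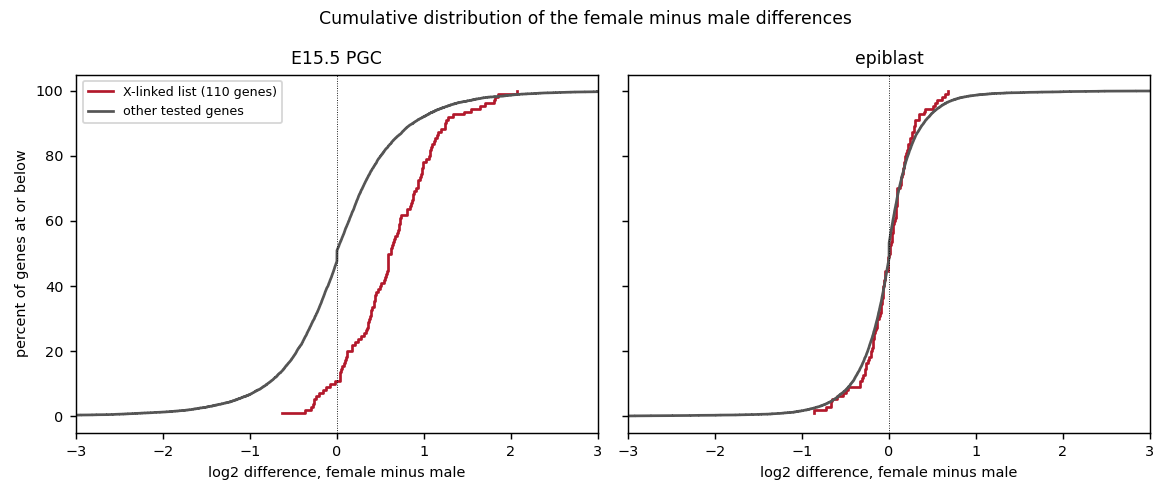
Curves give the cumulative share of genes against the female minus male log2 difference for 110 X-linked genes (red) and the other tested genes (grey), in E15.5 PGC and in epiblast. The red curve lies to the right at E15.5, with a median of 0.61, and has a median of 0.00749 in epiblast.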

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

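The comparison of the sex difference between stages was planned. Both tests on X-linked genes were written before their result, but were run on a list from general knowledge in place of the planned one from chromosome annotation, while the 3 tests on Y-linked transcripts were chosen only after the result was seen.

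In 15 named genes and 4 gene lists, the female minus male log2 difference at E15.5 differed from that in epiblast by a direct test in limma, with 2 female and 2 male libraries at E15.5 and 2 and 4 in epiblast. The difference of the differences was positive for Stra8 (6.39), Gata2 (5.24), Id1 (4.78), Id2 (4.59), Id4 (4.40), Ccnd2 (4.18), Pdk1 (3.51) and Kit (1.81). It was negative for Lefty2 (-4.70), Uba1y (-4.44), Ada (-4.38), Nr4a1 (-3.56), Wnt3 (-3.15), Fos (-2.36) and Utf1 (-1.26). The medians of the lists were 1.63 for fetal oocyte genes, 0.98 for BMP and SMAD response genes, -0.85 for dissociation and heat stress genes and 0.61 for X-linked genes. Stage and cell type changed together between epiblast and E15.5 PGC, so the design does not separate them. The 15 genes were named because they passed this same test, so that all 15 passed was fixed by the choice. With the compared libraries alone 4 of them did not pass, and leave-outs ended calls too, as given above.

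X-linked genes were higher in female than in male PGC at E15.5, with a median that lay 0.607 above that of the other genes as deposited, and had a median of 0.00749 in epiblast. After quantile normalization the value was 0.717 and so not under that of the deposited values, 0.607. The method moves X-linked and other genes of like level together. It therefore argued only against a scaling of the libraries that differs with the level of a gene. The median of ratios (0.607) and the TPM scale (0.637) multiply a whole library, so they shift both sets of genes nearly alike and decide nothing here. The doubtful male label in epiblast was argued against as well, since the epiblast median was 0.000507 without that library. A hypothesis that stays open is that both X chromosomes may be active in female PGC at E15.5, a difference of sex that the design names but that was not tested at the chromosome, since the 110 genes came from general knowledge and Xist was not among the tested genes.

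The epiblast library labelled male replicate 2 at E7.25 had Eif2s3y at 0 RPKM, against 117.6 to 165.8 RPKM in the 5 other male-labelled libraries and at most 0.140 RPKM in the 4 female-labelled ones. A swap with the female library of the same day was argued against, since that library had 0.0466 RPKM. Low depth was argued against too, since the library had 105% of the depth of male replicate 1. A single wrong sex label may account for it, as the value of 0 lies within the female-labelled range, and a loss of the Y chromosome stays open as untested. The library was kept as labelled.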

How the results depend on the processing

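The fits without the E10.5 and E11.5 libraries and those without small RNA genes were chosen only after the data were seen; the other alternatives were planned. For each changed result the cause was not tested. By construction, fits on the compared libraries alone have fewer libraries to estimate the spread, and take it from the compared groups only. Adjustment over all comparisons together pools their p-values, and filters and a minimum fold change alter the number of genes that can pass.

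Over all settings, 9444 values of 281 named gene results were compared with the main ones: 8946 kept their direction and their side of the threshold, 473 no longer passed, 18 newly passed and 7 reversed, the last all for genes that had not passed. Of 261 calls, 125 ended with the compared libraries alone, 39 with a pseudocount of 0.1, 12 with 0.5, 11 without a filter, 8 without a variance trend, 6 under quantile normalization, 5 on the TPM scale and 0 under the median of ratios. Sall4 at E9.5 against E7.75 epiblast changed from -0.09 to 0.060 on the TPM scale and 0.10 under quantile normalization, with -0.59 to 0.40 over the libraries left out. Sox2 there ranged from -0.18 to 0.52. Bmp4 at E11.5 against E10.5 changed from -0.16 to 0.10 on the TPM scale and 0.070 under quantile normalization.

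The number of genes that passed changed by over 1.5 times as follows. With the compared libraries alone it was 9 between the epiblast days, 2204 for E9.5 PGC against E7.75 epiblast, 0 for E10.5 against E9.5, 56 for E11.5 against E10.5, 0 for E12.5 against E11.5, 0 between the sexes at E15.5 and 150 between the sexes in epiblast; at an unadjusted p under 0.05 the main fits had 5915, 3080 and 3274 genes in the 3 comparisons at 0. With a minimum log2 fold change of 1 it was 3626 for PGC against epiblast, 2651 for E9.5 PGC against E7.75 epiblast, 632, 578 and 1376 for the steps to E11.5, E12.5 and E15.5. With adjustment over all comparisons together it was 370 between the epiblast days, 142 between the sexes in epiblast and 971 for the difference of the sex differences, for which no filter gave 768. Between the sexes in epiblast it was also 16 with a pseudocount of 0.1, 220 without a filter, 5 with a filter of 5 RPKM, 5 without the E10.5 and E11.5 libraries and 0 without small RNA genes (686 at an unadjusted p under 0.05 by limma with these kept). Between the epiblast days it was 12 without the E10.5 and E11.5 libraries.

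With each library left out in turn it ranged from 16 to 50 between the epiblast days, 8047 to 8783 for PGC against epiblast, 3249 to 4373 for E9.5 PGC against E7.75 epiblast, 3469 to 4425, 347 to 1357, 219 to 1313 and 884 to 2476 for the later steps in order of age, 445 to 1463 between the sexes at E15.5, 2 to 23 between the sexes in epiblast and 162 to 583 for the difference of the sex differences.

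The number of lists that passed was, with the preset correlation, 4 between the epiblast days, 16, 7, 4 and 12 for the steps to E10.5, E11.5, E12.5 and E15.5, 11 between the sexes at E15.5, 4 in epiblast and 9 for their difference. With fry it was 4 between the epiblast days, 23 for PGC against epiblast, 21, 24, 13, 10 and 14 for the steps from E9.5 on, 11 between the sexes at E15.5 and 8 for the difference. Under quantile normalization 1 list passed between the epiblast days. Of 50 list calls 49 held under quantile normalization, where glycolysis at E9.5 against E7.75 epiblast ended (adjusted p = 0.145), and 47 with the block, where BMP (0.0646) and oxidative phosphorylation genes (0.0563) at E10.5 against E9.5 and gonadal germ cell genes at E12.5 against E11.5 (0.0554) ended; none reversed.

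With the replicate number as a block, 5 genes passed between the sexes in epiblast and 1 list for E12.5 against E11.5, and 5 named calls ended. The numbers do not pair the samples: over 28 pairs of groups the correlation of deviations was -0.133 to 0.0581 and 0 pairs exceeded 0.1.

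In other splits of the samples, the 6 epiblast libraries fitted alone gave 9 genes between the days and up to 15 in another split, the one that sets the 3 libraries with Y-linked transcripts against the rest; 2 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For PGC against epiblast as 2 groups, 5997 genes passed and at most 1 in any other of the 100 splits, 1 of which (the real one) gave as many. The other splits put PGC and epiblast libraries together in a group, which widens the spread within it. Their low counts were thus largely fixed in advance, and nothing is concluded from them. Depth can limit the low genes of E10.5 and E11.5, at 20.7% to 23.0% of the reference library.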

Other observations

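The 7 gene lists described first, with 70 list tests, were chosen only after the values were seen. Their adjusted p-values come from those same values, so they describe these data and are no independent test. The comparison of E12.5 with E9.5 and the test on the PGC identity list were also chosen after the values were seen. The tests on the E10.5 and E11.5 libraries were written before their result.

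Genes of antigen processing and of the interferon response were higher in PGC than in epiblast. Of 36 such genes 32 rose and 1 fell (median log2 fold change 2.62, limma camera adjusted p = 0.00253), among them Isg15 (5.47 ± 0.16), Ifitm3 (5.43 ± 0.18), Isg20 (5.08 ± 0.16) and the proteasome activator gene Psme1 (4.79 ± 0.11). At E9.5 against E7.75 epiblast 28 rose and 0 fell (median 2.35, adjusted p = 0.00181). At E15.5 against E12.5, 2 rose and 14 fell (median -0.73, adjusted p = 0.0212), with the immune proteasome genes Psmb10 (-2.66 ± 0.18) and Psmb9 (-2.51 ± 0.34) and the peptide transporter gene Tap1 (-2.27 ± 0.46). At E15.5, 9 were lower and 0 higher in female PGC (median -0.68, adjusted p = 0.0212), among them Mx2 (-1.81 ± 0.44), Isg15 (-1.54 ± 0.32), Psmb8 (-1.48 ± 0.22) and Ifit1 (-1.45 ± 0.22). For this list the difference from the sex difference in epiblast did not pass (0 higher and 4 lower, median -0.43, limma camera adjusted p = 0.0601). Ifitm3 belongs to a family of similar copies and is uncertain.

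Of 17 targets of WNT signalling 9 rose at E15.5 against E12.5 (median 1.08, limma camera adjusted p = 0.00729), among them Sp5 (3.31 ± 0.60), Nkd1 (2.85 ± 0.35), Wif1 (2.25 ± 0.35) and Axin2 (1.60 ± 0.37). At E15.5, 4 were higher in female PGC (median 0.83, adjusted p = 0.023), among them Cdx2 (2.96 ± 0.53), Cdx1 (2.74 ± 0.53) and Ccnd1 (1.63 ± 0.29), and the difference from the sex difference in epiblast passed as well (median 1.0, adjusted p = 0.0212). Of 37 lysosome and autophagy genes 16 rose and 1 fell at E9.5 against E7.75 epiblast (median 0.61, adjusted p = 0.0212), with Ctsh (2.72 ± 0.26) and Lamp2 (2.48 ± 0.20). No test passed for the lists of cholesterol synthesis, of p53 targets and apoptosis, of FGF and MAPK feedback, or of metallothionein, glutathione and redox genes.

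The many changes between E9.5 and E10.5 coincided with a drop in depth, since the E10.5 and E11.5 libraries had 20.7% to 23.0% of the reference depth. If this or a batch were the whole cause, the change should be lost at E12.5. Of 1535 genes that passed as higher with E9.5 replicate 1 alone, 72.1% were also higher in E12.5 than in the other E9.5 library, and of 2123 lower ones 71.6% were lower; with the replicates exchanged these were 53% of 1534 and 69.3% of 2217. The values lie between the bounds set beforehand, 50% for a technical cause and 75% against it, so depth or batch and development cannot be told apart for these genes. Other embryonic cells in the E9.5 libraries may also account for the genes that fell, but the 17 PGC identity genes, which would then rise together, had a lower quartile of -0.55, a median of -0.21 and an upper quartile of 0.99, which leaves this open too, as it does development.

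E12.5 against E9.5, 2 ages of similar depth, gave 3449 genes in limma, 1675 higher and 1774 lower, and 3656 without the E10.5 and E11.5 libraries. Genes passing in both this comparison and that of E10.5 with E9.5 numbered 562 higher, 1155 lower and 109 in opposite directions. Of the genes that passed between E10.5 and E9.5, 78.0% had the same sign at E12.5. Among the named ones, Mest (-0.44 ± 0.64), Uqcrq (0.17 ± 0.21) and Id3 (0.093 ± 0.15) did not pass at E12.5 against E9.5. The other named genes that had passed did so again in the same direction. Of the 10 lists that passed between E10.5 and E9.5, 9 passed the same way, and oxidative phosphorylation did not (camera adjusted p = 0.958). Both comparisons subtract the same E9.5 libraries, so that genes and lists agree in part without a change shared by E10.5 and E12.5, and this part was not measured. The tests above, which take the calls and the direction from different E9.5 libraries, gave 53% to 72.1% and left the cause open.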
